A study of Cuscuta campestris with 9 samples.

How the data were processed

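Small RNA was sequenced from Cuscuta campestris (dodder), a rootless parasitic plant that attaches to host stems and leaves through feeding organs called haustoria. Per the labels' protocols, the parasite was grown in a greenhouse on beet and Coleus, and shoot tips of 6 to 8 cm were cut. One group of tips was frozen directly. For the other 2 groups, tips were pressed onto 3% agarose under 8 glass slides, given far-red light for 2 h and kept in darkness for 4 days, which induced haustoria, either with detached Arabidopsis thaliana leaves laid on the tips or without any host. Each of the 3 groups had 3 libraries, described in the labels as biological replicates. Per the labels' protocols, libraries were made by random-splint ligation from 5 µl of total RNA at 100 ng per µl, pooled, and size-selected at 150 to 190 bp for inserts of 12 to 52 nt.

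The deposited table gave, per the file headers, a read count for each locus in each library, the number of mapped reads in that library, and the level in the reads-per-million unit of mapped reads (RPM). The authors' RPM equalled the deposited count relative to the deposited mapped reads in all 1404 rows, within a tolerance of 1e-06. Per the submitters' processing notes, cutadapt 3.5 and Bowtie were used; the version of Bowtie, the way reads with several mapping places were assigned, and the way the loci were chosen are not given in the sources used here. The scaffold names carry the assembly name Ccam0.32, and coordinates are those of the table. The available gene annotation was of another assembly of the species, so the genes around each locus were not analysed here.

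The table held 156 loci of 80 to 130 nt (median 89.0) on 75 scaffolds. Of these, 64 had names with a miR number and 92 had names with IIM, an abbreviation that the sources used here do not spell out. By name they formed 103 families, of which 39 had 2 or more loci. Near-identical copies may share reads, and locus values within such families are uncertain to that extent. Because the loci could have been chosen on samples of this kind, the direction of change of the whole table is not independent evidence.

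Mapped reads per library ranged from 10520587 to 19244971. A locus with 0 reads in all shoot tips was given a floor of 3 counts over the group, or 0.0716 RPM, and folds against such a locus are lower bounds. For loci with 1 to 3 reads in all shoot tips together, the ratio of pooled reads is given with an exact 95% interval. Library intervals are exact binomial. These intervals and floors cover counting error only, since PCR copies of reads were not marked.

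Differences were tested on counts with edgeR 4.0.16 in R 4.3.3 by its robust quasi-likelihood test, two-sided, with all 9 libraries in 1 fit and a mean per group. Loci passed edgeR's default expression filter (minimum count 10, minimum total 15), which kept 153 and left out 3. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The groups, tests, alternatives, lists and the rule for naming loci were fixed before the data were examined, with TMM scaling as the planned library scaling. That scaling assumes that most features do not change, and the table holds only part of each library, so the deposited mapped reads were used as library sizes without a further factor. This departure was decided after the table was seen; the splits of calls under TMM and the other scalings over the table's own loci are printed beside the main ones.

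Alternatives were 4 scalings over the loci of the table (TMM, DESeq2 size factors, total counts, upper quartile), DESeq2 1.42.0, limma-voom with limma 3.58.1, no filter, a filter of 10 CPM in 3 libraries, a test against a fold of 2, only the 6 libraries compared, the replicate number as a block, and each library left out in turn. TMM, the planned main scaling, became an alternative when mapped reads took its place after the table was seen. Added after the data were seen were TMM with only 6 libraries, copies of a family summed, the list's estimated correlation under each scaling, and the share of mapped reads without its leading locus or 1 library. Composition was compared with exact two-sided permutation tests in SciPy 1.17.1 under Python 3.11.15; with 3 against 3 libraries the smallest possible p is 0.1.

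Loci were named by rule: for each comparison, the 10 largest increases and 10 largest decreases past the threshold with no overlap between the libraries of the groups and a mean of at least 10 RPM in the higher group, the 5 loci with the highest mean RPM, and the 10 most abundant members of a fixed list of microRNA families known from earlier work on haustoria. Exceptions are marked in the text. That list named 6 families and had 15 loci in the table. It was tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry. The other 7 lists (conserved plant microRNAs, and microRNAs linked to auxin, development, nutrients and copper, silencing, immune receptors, and the Arabidopsis host) had 0 loci in the table and were not tested.

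The test was checked on simulated counts for 153 loci, 16 at each fold. For haustoria with against without a host it recovered 2 of 16 loci changed 2-fold, 12 of 16 changed 4-fold and 16 of 16 changed 100-fold, and called 2 of 105 unchanged loci. For haustoria without a host against shoot tips it recovered 1, 5 and 16 of 16, and for haustoria with a host against shoot tips 0, 9 and 16 of 16, with 0 of 105 unchanged loci called in either. In each of these checks the group outside the comparison was simulated at the level of the comparison's second group. For the comparison between haustoria, the simulated shoot tips thus had haustorial levels, unlike those in the data. The rates of recovery may therefore differ in the data. The list test was checked with the fixed list in 100 simulated data sets, for haustoria with against without a host only. It called 0 with no effect and 100 with a 2-fold effect. Loci were simulated as independent, whereas the list's estimated correlation in the data was 0.318. These rates therefore do not carry over to the real list test.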

Results

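The accumulation of 156 microRNA loci of Cuscuta campestris was compared among shoot tips, haustoria induced in vitro without a host, and haustoria induced with Arabidopsis leaves, with 3 libraries per group. MicroRNAs are short RNAs cut from hairpin precursors that lower the expression of matching messenger RNAs, and some haustorial microRNAs of this parasite are known to act on host messenger RNAs. Mapped reads per library ranged from 10520587 to 16706210 in shoot tips, from 10680833 to 14336549 in haustoria without a host and from 11201536 to 19244971 in haustoria with a host, and levels are given in the reads-per-million unit of mapped reads (RPM).

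Reads at the loci were rare in shoot tips and abundant in both kinds of haustoria. They made up 0.0322% ± 0.0099 of mapped reads in shoot tips (SD, n = 3), 5.80% ± 1.25 in haustoria without a host and 7.38% ± 2.48 in haustoria with a host. The share was 180-fold higher without a host and 229-fold higher with a host than in shoot tips (exact permutation p = 0.1 for each, the smallest this design allows; 0.2 after adjustment over 18 composition tests). Haustoria with and without a host differed in this share by 1.27-fold, and their libraries overlapped (exact permutation p = 0.5). The difference of 1.58 percentage points was above the SD without a host and below that with one. Without haustoria with host replicate 3, which had the highest share at 10.2%, the ratio was 1.03. The number of loci without a read was 63, 54 and 35 in the shoot tip libraries and at most 3 in any haustoria library.

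**Figure D1:**
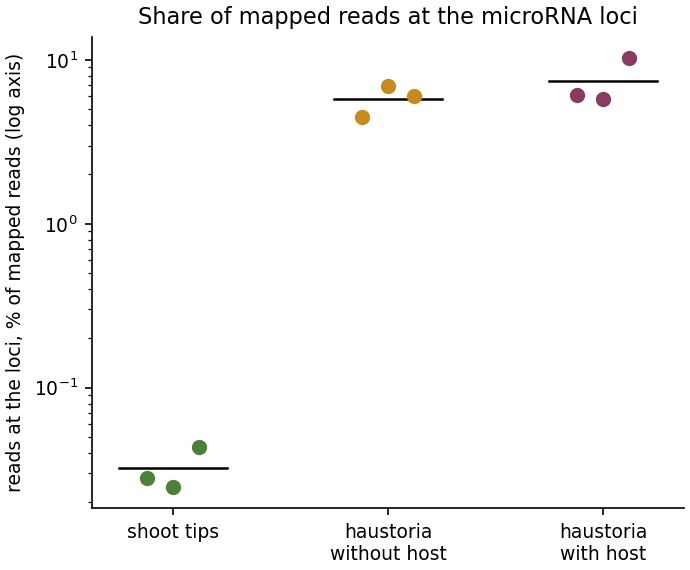
Percent of mapped reads at the 156 loci in each library (points; log axis), with the mean of each group of 3 as a line. Shoot tips lie between 0.0249% and 0.0435%, and the haustoria libraries between 4.46% and 10.2%.

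A few loci made up much of the reads at the 156 loci in each group. These are not shares of all microRNA reads of a tissue, since the conserved plant microRNA list had 0 loci in the table. The locus miR12490a (scaffold 59, 1855139 to 1855224) was the most abundant in haustoria, at 17273 ± 3414 RPM without a host and 20238 ± 5538 RPM with a host, against 80.1 ± 21.3 RPM in shoot tips (SD, n = 3). It took 29.9% ± 1.84 of the locus reads without a host, 27.9% ± 4.57 with a host and 25.3% ± 5.15 in shoot tips. The locus miR12497f (scaffold 111, 801311 to 801398) took a larger share of the locus reads in shoot tips, 23.7% ± 4.64, than in haustoria, where it took 6.20% ± 1.05 without a host and 7.07% ± 0.77 with one; the libraries of shoot tips and haustoria did not overlap in this share.

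The first comparison asked which microRNAs differed between shoot tips and haustoria formed with no host present. Shoot tips were frozen directly. Both kinds of haustoria came from tips kept on agarose under slides, with far-red light and 4 days of darkness. Haustorium formation and this treatment therefore cannot be told apart in either comparison with shoot tips. Of 153 loci tested, 145 were higher in haustoria without a host than in shoot tips and 0 were lower. Because the loci could have been chosen on samples of this kind, this shared direction is not independent evidence. The 10 largest increases were taken by fitted log2 change, which does not order loci with few or no shoot tip reads among themselves. They included miR12479a (scaffold 26, 2523691 to 2523780), IIM-98, IIM-10a and IIM-10b, none of which had a read in any shoot tip library. Their levels in haustoria without a host were 60.6 ± 18.1, 49.0 ± 13.2, 42.0 ± 8.12 and 41.8 ± 10.7 RPM (SD, n = 3), at least 847-, 685-, 587- and 584-fold higher than in shoot tips. The loci miR12475, IIM-61a, IIM-61b and IIM-96a also had 0 shoot tip reads and were at least 450-, 395-, 387- and 371-fold higher. These bounds rest on the shoot tip reads available: without shoot tip replicate 2 or 3 the floor rose to 0.110 or 0.119 RPM, and the bound for miR12479a fell to 550 or 509. IIM-61a and IIM-61b had counts equal within sampling noise, so their separate values are uncertain. The locus miR12465b rose from 0.131 ± 0.153 to 617 ± 180 RPM, a 4692-fold ratio of means that rests on 6 shoot tip reads and was 12977 without shoot tip replicate 3 and 3128 without shoot tip replicate 2. The locus miR12477 had 3 reads in all shoot tips together and a pooled ratio of 3982 (95% counting interval 1362 to 19312).

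Abundant loci rose as well. On the log2 scale, the increase was 7.75 ± 0.60 (SE) for miR12490a, 8.85 ± 0.84 for miR12487b, 5.60 ± 0.68 for miR12497f, 9.06 ± 0.96 for IIM-51 and 9.19 ± 0.95 for miR12492a (edgeR adjusted p at most 1.1e-10 in all 5); that of miR12497f turned to lower under all 4 scalings on the table's loci. Without shoot tip replicate 3, which had the most reads of both, the change was 10.17 for miR12487b and 10.58 for IIM-51. Over all loci tested the median fitted log2 change was 7.46, and the median fold was 153 with the 22 loci lacking shoot tip reads set at their bounds. Without shoot tip replicate 3 the median log2 change was 8.13. All 3 haustoria libraries lay above all 3 shoot tip libraries for 147 of 153 loci. Chance gives 5% of loci in this direction, but loci of a library share its scaling and are not independent. The loci could also have been chosen on samples of this kind, so the 5% does not measure how unusual the 147 are. Among the 5 loci most abundant in shoot tips, IIM-87 (chosen after its values were seen) changed least, from 14.7 ± 2.33 to 91.2 ± 35.4 RPM, a log2 change of 2.64 ± 0.66, which turned to lower under all 4 scalings on the table's loci.

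The direction of these changes is relative to mapped reads. When libraries were scaled on the loci of the table alone, the median log2 change fell from 7.46 to 0.76 with TMM, 0.54 with DESeq2 size factors, 0.24 with total counts and 0.18 with upper quartiles. The higher and lower calls then numbered 48 and 35 with TMM, 42 and 36 with DESeq2 size factors, and 34 and 39 with either of the other scalings.

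The second comparison asked the same of haustoria formed against host leaves. Of 153 loci, 151 were higher in haustoria with a host than in shoot tips and 0 were lower. The limit from the unknown choice of loci applies here too. The 10 largest by fitted change again included miR12479a and IIM-98, at 98.1 ± 28.9 and 91.0 ± 27.3 RPM (SD, n = 3), at least 1371- and 1272-fold above shoot tips. The loci miR12475, IIM-10b, IIM-61b, IIM-61a, IIM-10a and miR12484 were at least 853-, 781-, 690-, 690-, 655- and 502-fold higher. These bounds too rest on the shoot tip reads available: without shoot tip replicate 2 or 3, that of miR12479a fell to 891 or 825, that of IIM-98 to 826 or 765 and that of miR12484 to 326 or 302, and the others fell by the same factors. Without haustoria with host replicate 3 the bounds were 465 for IIM-61a and 451 for IIM-61b. With 3 and 1 shoot tip reads, miR12477 and miR12485 had pooled ratios of 7355 (95% counting interval 2516 to 35667) and 6976 (1252 to 275559). The ratio of means of miR12485 was 6670, and 4119 without haustoria with host replicate 3; without shoot tip replicate 2, which held its only shoot tip read, it was at least 1374-fold higher. The log2 change was 7.98 ± 0.61 (SE) for miR12490a, 8.98 ± 0.85 for miR12487b, 6.14 ± 0.70 for miR12497f, 9.14 ± 0.96 for IIM-51 and 9.65 ± 0.97 for miR12492a. Without shoot tip replicate 3 it was 10.30 for miR12487b and 10.65 for IIM-51. The loci not past the threshold, named after their values were seen, were IIM-80 (log2 1.52 ± 0.91, edgeR adjusted p = 0.10) and miR12497g (0.85 ± 0.81, adjusted p = 0.30); both turned to lower under all 4 scalings on the table's loci, as did miR12497f, and miR12490a did so with upper quartiles. Without shoot tip replicate 2 the change of IIM-80 was 2.40 and passed the threshold, and without shoot tip replicate 3 that of miR12497g was 1.59 and did not.

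The median fitted log2 change against shoot tips was 8.07 with a host, and the median fold was 238 with unread loci at their bounds; without shoot tip replicate 3 the median log2 change was 8.67. Under the scalings on the table's loci, this median was 0.60 with TMM, 0.50 with DESeq2 size factors, 0.31 with total counts and 0.05 with upper quartiles. The higher and lower calls were then 51 and 31, 49 and 32, 42 and 34, and 36 and 38.

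**Figure D2:**
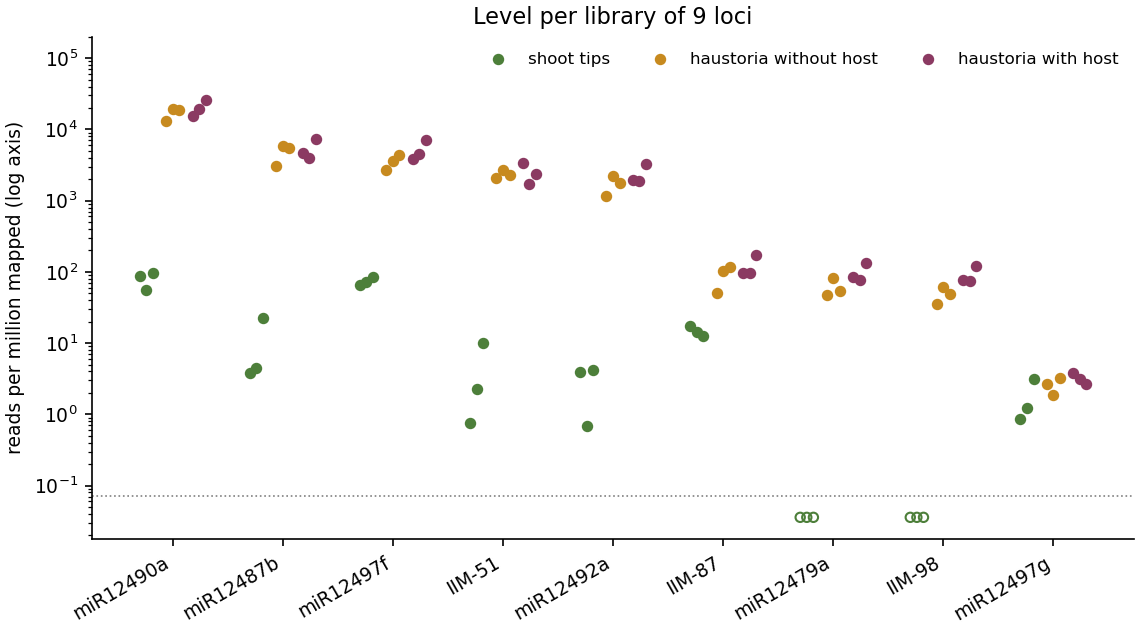
RPM (log axis) of 9 loci in each library, by group. Open circles are libraries with 0 reads, drawn below the dotted line, which marks the shoot tip group floor of 0.0716 RPM; miR12479a and IIM-98 had no shoot tip reads, and the miR12497g libraries overlap between groups.

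The same 145 loci were higher in both kinds of haustoria, 6 more passed the threshold only with a host, and 2 passed in neither. Under the scalings on the table's loci, only 73 loci (TMM), 71 (DESeq2 size factors), 66 (total counts) and 67 (upper quartiles) were called in 1 direction in both. None of the 6 loci called only with a host passed the threshold in the main fit's direct comparison of haustoria with and without a host; 1 of them, IIM-42, did so in some of the alternatives described below. Independent lists of these sizes would share 143.1 loci, so the overlap was nearly fixed by the sizes of the lists. In simulation, 100 pairs of unchanged groups against the same shoot tips shared at most 0. Those groups were drawn from the means of the same shoot tips, so calls were unlikely in advance. The simulation therefore does not measure what the shared tips add to the overlap. Part of any excess may come from the shared shoot tip libraries.

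The fixed list of families known from haustoria (miR12480, miR12494, miR12495, miR12496 and miR12497) rose with the rest. In each comparison with shoot tips 14 of its 15 loci were higher and 0 were lower, 14 also when adjusted over the list alone; miR12497g did not pass. Its members had been described in haustoria before, so this direction is not independent evidence. Some of the other loci, such as miR12479a and miR12493, carry neighbouring miR numbers. Whether they too were described in haustoria before was not examined. The other loci therefore cannot be taken as a background without haustorial microRNAs. The increase without a host was 10.16 ± 1.11 (log2, SE) for miR12494b and 9.68 ± 1.02 for miR12495a, whose counts equalled those of miR12495b within sampling noise. It was 7.45 ± 0.87 for miR12480b, 7.08 ± 0.84 for miR12480c, 6.93 ± 0.83 for miR12496 and 5.45 ± 0.77 for miR12480a. Within the miR12497 family it was 6.76 ± 0.84 for miR12497e, 6.28 ± 0.79 for miR12497d and 5.60 ± 0.68 for miR12497f. With a host these values were 10.11, 10.65, 8.28, 7.69, 8.09, 6.43, 7.27, 6.22 and 6.14. Without shoot tip replicate 3 the change was 11.94 without a host and 11.89 with one for miR12494b, and 11.42 and 12.40 for miR12495a; without shoot tip replicate 2 it was 9.57 and 9.53, and 9.09 and 10.07.

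Relative to the median of all loci, miR12494b lay 2.70 above without a host and 2.05 above with one, and miR12495a 2.22 and 2.59 above. The locus miR12497f had a relative log2 change of -1.85 without a host and -1.92 with one, and miR12480a of -2.00 and -1.64; the directions of both against shoot tips turned to lower under all 4 scalings on the table's loci. The loci miR12497d and miR12497e also did so under all 4, as did miR12496 without a host; miR12496 with a host, and miR12480b and miR12480c, did so under fewer or none of them. The list's median log2 change, 6.76 without a host and 7.27 with one, lay below the medians of the other loci, 7.62 and 8.11, although camera gave the list an upward sign (limma's camera, adjusted p = 0.84 in both; 0.93 with an estimated correlation). That sign was downward, without a call, under the filter of 10 CPM. Under the 4 scalings on the table's loci the camera sign was downward, with adjusted p between 0.00698 and 0.014. With a correlation estimated under each scaling, adjusted p = 0.038 with total counts and 0.043 with TMM, but 0.053 with upper quartiles and 0.10 with DESeq2 size factors, where the call was lost. The list took 30.9% ± 4.56 of locus reads in shoot tips and 13.5% ± 1.29 and 15.5% ± 1.31 in haustoria without and with a host (SD, n = 3; exact permutation p = 0.1 for each comparison with shoot tips). This fall lay in miR12497f: the other 14 members took 7.21% ± 0.135 in shoot tips, 7.34% ± 0.699 without a host and 8.42% ± 0.860 with one.

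**Figure D3:**
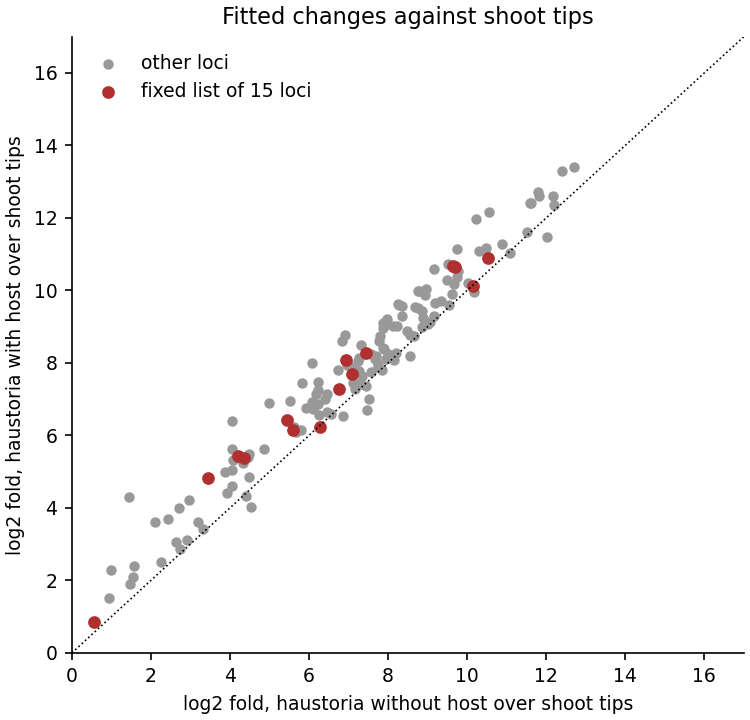
Fitted log2 fold of each of 153 loci against shoot tips, in haustoria without a host (horizontal) and with a host (vertical), with mapped reads as library size; red points are the 15 loci of the fixed list and the dotted line marks equal change. All estimates are above 0, but the medians of 7.46 and 8.07 fell to 0.76 and 0.60 with TMM scaling, where miR12497f and other loci turned to lower.

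The third comparison asked whether the presence of host leaves altered the microRNAs of haustoria. No locus passed the threshold in edgeR (0 of 153; 12 at an unadjusted p under 0.05, all higher with a host), while DESeq2 called 1 (22 unadjusted) and limma-voom called 0 (12 unadjusted). The most abundant loci gave small estimates: the log2 change with a host was 0.23 for miR12490a (95% CI -0.67 to 1.13), 0.13 for miR12487b (-1.07 to 1.34), 0.54 for miR12497f (-0.58 to 1.66), 0.07 for IIM-51 (-1.29 to 1.43) and 0.45 for miR12492a (-0.88 to 1.79). Their signs are not settled: under all 4 scalings on the table's loci those of miR12490a, miR12487b and IIM-51 turned negative, with TMM also those of miR12497f (-0.019) and miR12492a (-0.068), and the latter with upper quartiles. These scalings move the loci down together, from a median of 0.64 to 0.10 with TMM, so small positive estimates turn negative. Leaving out 1 haustoria library also turned the signs of miR12490a, miR12487b and IIM-51. For all loci the median half-width of the interval was 1.34 on the log2 scale, with the spread estimated over all 9 libraries, shoot tips included.

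Estimates were nonetheless mostly on 1 side. The estimate was above 0 for 139 loci and below 0 for 14, with a median of 0.64. For 50 of 153 loci all 3 libraries with a host lay above all 3 without, and for 0 the other way. Chance gives 5% in each direction. Loci of a library share its scaling, so this rate does not measure how unusual the 50 are. The median was 0.37 without haustoria with host replicate 3. With TMM scaling it was 0.10, with 87 estimates above and 64 below 0, and with TMM in only the 6 haustoria libraries it was -0.057, with 73 above and 80 below. Loci of the fixed list had a median log2 change of 0.83, and 0 of 15 passed the threshold, also when adjusted over the list alone. No difference of the list from the other loci was detected (limma's camera, adjusted p = 0.84). The list summed to 11276 ± 3104 RPM with a host and 7892 ± 1988 without (SD, n = 3), 1.43-fold (exact permutation p = 0.1, adjusted 0.2). Its members included miR12496 at 1.16 ± 0.64 (SE) and miR12495b at 1.04 ± 0.68, against -0.05 ± 0.74 for miR12494b and -0.06 ± 0.62 for miR12497d, both of which turned positive when certain single haustoria libraries were left out.

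The largest estimate was at IIM-42 (scaffold 60, 1169248 to 1169334), named after its values were seen, at 1.79 ± 0.94 RPM without a host and 13.02 ± 11.4 RPM with one (SD, n = 3). Its log2 change was 2.85 ± 0.79 (SE; edgeR adjusted p = 0.11), it was higher in 3 of 3 libraries, and without haustoria with host replicate 3 its change was 1.84. It was the locus called by DESeq2 and by edgeR when any 1 shoot tip library was left out. When only the 6 haustoria libraries were fitted, 8 loci were called higher: IIM-12b, IIM-29, IIM-35a, IIM-42, miR12468, miR12479b, miR12484 and miR12485. In the fit of all 9 libraries less 1, that of miR12485 moved from 1.61 to 0.91 without haustoria with host replicate 3, and without haustoria without host replicate 2 those of IIM-35a and miR12484 moved from 2.37 to 3.38 and from 1.74 to 2.79. Among these 8 miR12479b was the most abundant, at 66.3 ± 32.5 RPM without and 251 ± 107 RPM with a host. With TMM scaling in those 6 libraries 0 were called, with 34 at an unadjusted p under 0.05.

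**Figure D4:**
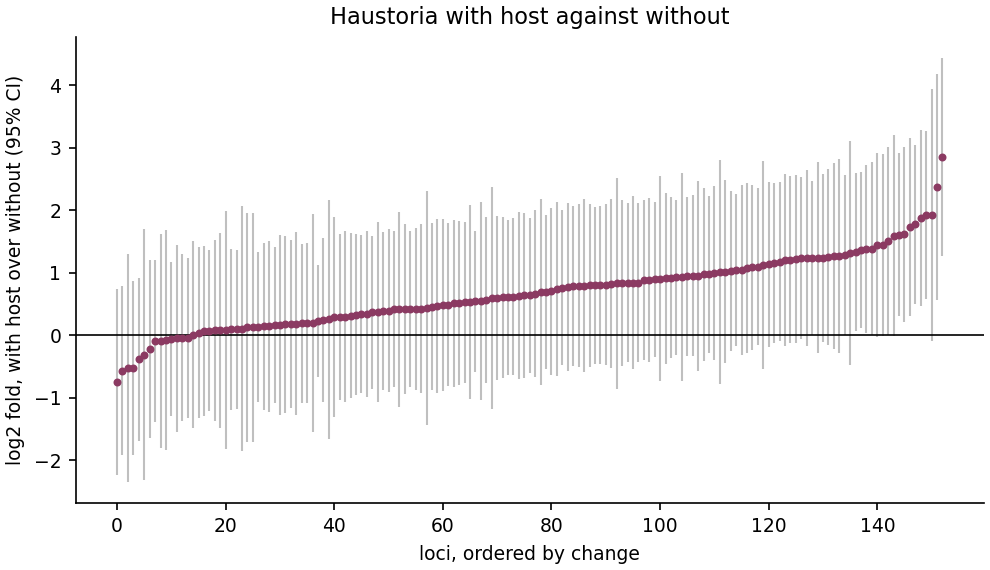
Fitted log2 fold, haustoria with a host over without, for 153 loci in order of size (points), with 95% confidence intervals (bars) and mapped reads as library size. The median is 0.64, against 0.10 with TMM scaling and -0.057 with TMM in only 6 libraries, and no locus passes the adjusted threshold.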

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

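TMM was the planned main scaling, and mapped reads took its place after the table was seen. TMM with 6 libraries, sums over copies, the list's estimated correlation under each scaling, and all alternatives for the share of mapped reads were added after the data were seen. The results depended most on the scaling. With mapped reads as library size, the loci called against shoot tips numbered 120 to 149 without a host and 120 to 152 with one over the other tests, filters and sample choices, with none lower; the 120 under the filter of 10 CPM are all the loci that it tested. Summing copies left 96 and 100 calls, and 96 in both, of 101 features, because fewer features were tested. Scaled on the table's own loci, calls in either direction numbered 83 with TMM, 78 with DESeq2 size factors and 73 with total counts or upper quartiles without a host, and 82, 81, 76 and 74 with a host. Loci called in 1 direction in both numbered 73, 71, 66 and 67. These scalings are computed from the loci themselves, so they give changes relative to the other loci.

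Leaving out 1 library gave 143 to 148 calls without a host, 147 to 152 with a host, 143 to 148 in both, and 0 to 1 between haustoria (the 1 was IIM-42, without any 1 of the shoot tip libraries). Between haustoria DESeq2 called 1, for a cause that was not tested, and the fit of only 6 libraries called 8. In that fit 39 loci had an unadjusted p under 0.05, against 12 in the main fit, at the same median of 0.64. Without shoot tip replicate 1, 2 or 3 the numbers were 25, 26 and 31, at a median of 0.65. Calls between haustoria thus depend on the spread that the shoot tips bring into the fit. The ratio of the share of mapped reads ranged from 162 to 218 without a host, 185 to 278 with one, and 1.03 to 1.41 between haustoria. With the replicate number as a block there were 145, 151 and 0 calls. The labels do not say whether a number marks a shared batch. Same-numbered libraries had correlations of deviations from -0.05 to 0.28, and not every library correlated best with its own number. Between haustoria with a host and shoot tips each did (0.13, 0.12 and 0.08). With 3 libraries per group this cannot decide whether the numbers pair the samples.

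For the fixed list, camera turned from upward to downward against shoot tips, with adjusted p of 0.012 with TMM, 0.014 with DESeq2 size factors, 0.00863 without a host and 0.00916 with one with total counts, and 0.00698 with upper quartiles. With an estimated correlation the call was lost with DESeq2 size factors (0.10) and upper quartiles (0.053). The sign was also downward, without a call, with the filter of 10 CPM (0.45 without a host and 0.51 with one) and, without a host, when haustoria without host replicate 3 was left out. Under fry, which asks only whether the members move one way, adjusted p was 1.4e-06 in both comparisons with shoot tips and 0.057 between haustoria. Leaving out 1 library gave camera adjusted p of 0.72 to 0.99 against shoot tips and 0.55 to 0.97 between haustoria.

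Of 1519 alternative values for named loci, 1389 kept their direction and side of the threshold, 23 lost and 14 gained the threshold, and 93 changed sign. Of these, 59 were against shoot tips, all under the scalings on the table's loci. In their new direction 14 of them passed the threshold without a host and 18 with one. The other 34 were between haustoria, none of them past the threshold. With TMM, the changes that turned negative without a host were -1.46 for miR12497f, -0.26 for miR12497e, -0.0022 for miR12496, -1.68 for miR12480a, -0.89 for miR12497d and -4.54 for IIM-87. With DESeq2 size factors, the changes that turned negative without a host were -1.73 for miR12497f, -0.50 for miR12497e, -0.083 for miR12480c, -0.20 for miR12496, -1.96 for miR12480a, -1.23 for miR12497d and -4.80 for IIM-87. With total counts, the changes that turned negative without a host were -1.93 for miR12497f, -0.0052 for miR12480b, -0.75 for miR12497e, -0.37 for miR12480c, -0.51 for miR12496, -2.13 for miR12480a, -1.37 for miR12497d, -4.98 for IIM-87 and -0.073 for miR12469b. With upper quartiles, the changes that turned negative without a host were -1.98 for miR12497f, -0.083 for miR12480b, -0.83 for miR12497e, -0.43 for miR12480c, -0.56 for miR12496, -2.18 for miR12480a, -1.43 for miR12497d, -5.05 for IIM-87 and -0.11 for miR12469b. With TMM, the changes that turned negative with a host were -1.48 for miR12497f, -0.17 for miR12497e, -1.24 for miR12480a, -1.38 for miR12497d, -6.04 for IIM-80 and -6.49 for miR12497g. With DESeq2 size factors, the changes that turned negative with a host were -1.67 for miR12497f, -0.29 for miR12497e, -1.45 for miR12480a, -1.65 for miR12497d, -6.36 for IIM-80 and -6.60 for miR12497g. With total counts, the changes that turned negative with a host were -1.75 for miR12497f, -0.47 for miR12497e, -0.10 for miR12480c, -1.49 for miR12480a, -1.68 for miR12497d, -6.37 for IIM-80 and -6.82 for miR12497g. With upper quartiles, the changes that turned negative with a host were -0.096 for miR12490a, -1.98 for miR12497f, -0.69 for miR12497e, -0.35 for miR12480c, -0.0019 for miR12496, -1.72 for miR12480a, -1.90 for miR12497d, -6.56 for IIM-80 and -7.05 for miR12497g. Between haustoria, the changes that turned negative were -0.30 for miR12490a, -0.38 for miR12487b, -0.019 for miR12497f, -0.37 for IIM-51 and -0.068 for miR12492a with TMM; -0.22 for miR12490a, -0.32 for miR12487b and -0.34 for IIM-51 with DESeq2 size factors; -0.098 for miR12490a, -0.19 for miR12487b and -0.20 for IIM-51 with total counts; -0.27 for miR12490a, -0.37 for miR12487b, -0.39 for IIM-51 and -0.045 for miR12492a with upper quartiles; -0.45 for miR12490a, -0.54 for miR12487b, -0.17 for miR12497f, -0.56 for IIM-51, -0.22 for miR12492a, -0.060 for miR12497e and -0.080 for miR12480c with TMM in 6 libraries. That of miR12497d turned positive, at 0.040 with limma-voom and 0.083 with the replicate block. Leaving out 1 library also turned signs, with changes from -0.0014 to 0.40 for miR12490a, -0.17 to 0.31 for miR12487b, -0.21 to 0.28 for IIM-51, -0.24 to 0.19 for miR12494b and -0.38 to 0.25 for miR12497d. Depth limits the shoot tip side: 22 loci had no read there and 13 had 1 to 3.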

Other observations

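The tests here of the carried reads, of replicate 3, of a shared factor, of equal copies and of the naming of loci, and of splits of the libraries, were chosen after the results they bear on had been seen; those of detection by level and of neighbouring loci were set before.

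Copies of a family differed widely in level. Among 39 families with 2 or more loci, the most abundant copy exceeded the least abundant by a median of 4.21-fold in mean haustoria RPM, by over 10-fold in 15 families and by over 100-fold in 5. The largest ratio was 1670, between miR12490a and miR12490b, followed by 1524 between miR12497f and miR12497g and 1232 between IIM-43a and IIM-43c. The 2 loci of each of these pairs lie on the same scaffold. These loci were named after their values were seen.

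Shoot tips had a low level of reads at the loci, at a median of 0.399% of the haustoria mean per locus. Haustorial reads carried into the shoot tip libraries at 1 share for every locus could bring at most 0.176%, the upper bound set by miR12477 with 3 reads. This share would account for at most 45.4% of the shoot tip reads at the loci, and 74 loci had more reads than it allows, among them miR12497g, at 60.1% of its haustoria mean, and IIM-87, at 13.8%. For the other 82 loci, carried reads and a low level in the tissue cannot be told apart at this depth: 22 had no shoot tip read, 45 had reads at or under the amount carried reads could bring, and 15 exceeded it by less than counting error (Poisson test, adjusted p of 0.05 or more). At the 74 loci the counts argue against reads carried at 1 share for every locus as the only source of the shoot tip reads. At the other 82, a low level in tips before haustoria form remains open. Sources other than such carried reads were not tested.

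Estimates were higher with a host than without at most loci, and 3 explanations were weighed. Without haustoria with host replicate 3 the median log2 change was 0.37 in place of 0.64, so this library may account for part of it. Detection of scarce loci in deeper libraries would raise scarce loci more: the median change of the 51 least abundant loci was 0.67 and that of the 51 most abundant 0.45, a difference of 0.21 (bootstrap 95% interval -0.10 to 0.61, loci taken as independent), which leaves this open. One factor shared by all loci, such as more haustorial tissue per sample, would leave few differences after scaling on the loci; 34 loci had an unadjusted p under 0.05 in the real grouping and at most 24 in the other groupings of the 6 libraries, 1 of 10 reaching the real number, too few for a share under 0.05. An effect of the host itself remains open.

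Some copies had equal counts. In 6 of 77 pairs of copies with at least 100 haustoria reads each, counts were split equally in every haustoria library within sampling noise: IIM-61a and b, IIM-73b and c, IIM-76a and b, IIM-79a and b, miR12495a and b, and miR12497a and b. Among pairs with totals within a ratio of 1.1, this held for 6 of 10 pairs of copies and for 2 of 284 pairs from different families (Fisher's exact p = 6.7e-09, with loci shared among pairs and so not independent). A candidate explanation is that these copies yield the same small RNA and that its reads were divided between them during mapping. Equal activity of both copies would give the same counts and was not tested.

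Loci of different families that lie within 20 kb of each other were tested for alike responses to the host. In 19 such pairs the mean absolute difference in log2 change was 0.53, against 0.65 for shuffled loci (one-sided permutation p = 0.155, 100000 shuffles). The prediction set before the test read such a p as evidence against shared regulation; a missed threshold with 19 pairs does not show that, so the question is left open.

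Loci with a miR number had a median haustoria level of 182 RPM (64 loci), against 41.5 RPM for the 92 loci named IIM (two-sided permutation test on mean log2 level, p = 6.0e-05, 100000 resamples, with copies not independent). A hypothesis is that abundant loci may have been found and numbered earlier; the sources used here do not give the order in which loci were found.

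The 6 libraries of each pair of groups were regrouped in all 10 ways. The comparison of haustoria without a host with shoot tips gave 145 loci, reached by 1 of the 10 splits, and at most 0 in the others. The comparison of haustoria with a host with shoot tips gave 151, also reached by 1 of 10, and at most 0 in the others. The comparison between haustoria gave 0, as did all 10 splits. With 10 splits the share cannot go under 0.05. The other splits against shoot tips mixed both tissues on each side, which raises the spread within sides. Their 0 calls therefore add nothing beyond the size of the difference.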
